A study of Homo sapiens with 26 samples.

How the data were processed

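U2OS osteosarcoma cells with an Arntl luciferase reporter were seeded at 375000 cells per dish, per the labels' protocols. They were changed to neutral (pH 7.4) or acidic (pH 6.3) medium with 5% serum, 25 mM PIPES, 25 mM HEPES and 0.1 µM dexamethasone and kept sealed without added carbon dioxide. RNA was taken every 4 h from 4 to 52 h. A first set of plates gave the 28 to 52 h samples and a second set the 4 to 24 h samples, and 4 h and 28 h, then 8 h and 32 h and so on, were collected together in both media. RNA integrity numbers ran from 8.7 to 10, with a median of 9.7, and libraries were made with a stranded kit for polyadenylated RNA.

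The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 26 libraries. Reads were aligned to hg38 with STAR and quantified with Cufflinks, per the submitters' processing notes. Their versions, the annotation release and the strand setting are not given in the sources used here. The table held 19806 rows, 98.1% of them protein coding in GENCODE 29. In all 19545 rows had an identifier in that annotation, which gave coordinates (GRCh38) and the GC content of transcripts. In 1448 rows every library was at 0, and 101 symbols were on more than 1 row, of which the row with the highest mean stands for the gene. The columns summed to 600589 to 700348 FPKM. No 2 libraries held identical values, and the correlation between libraries across genes ran from 0.83 to 0.99.

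Total counts are not in the table. Depth was estimated from the spacing of low FPKM values in 1829 genes with a single transcript of at least 1000 bases. The value of 1 fragment was taken to depend on the transcript length minus 200 bases. Between 83.5% and 94.9% of the values up to 3.5 fragments then lay within 0.1 of a whole number. The estimates were 61.4 to 105 M fragments (M for mega) for 24 libraries and 9.71 and 11.1 M for pH 7.4 at 12 h and pH 6.3 at 8 h. Count tests were not used, because FPKM are not counts.

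Values were tested as log2(FPKM + 1) for the 11849 genes with a mean of at least 1 FPKM over the 26 libraries, with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend in the mean) and Benjamini-Hochberg adjustment at 0.05. The acid effect was the mean of 13 differences within time points, with the time point as a block because both media of a time point were harvested together. Its difference between 4 to 24 h and 28 to 52 h was the interaction of pH and plate set. Rhythms were tested with cosine and sine terms of 24 h in 1 fit of both media, with a linear trend for each pH, and the difference between media with the difference of those terms. Each dish gave 1 library and no time point had replicates, so p-values measure the spread over time points.

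The design, the tests, the alternatives and the gene lists were fixed before the data were examined. The 29 lists were the core clock, glucocorticoid targets, cholesterol synthesis, fatty acid synthesis, ATF4 targets, endoplasmic reticulum stress, hypoxia, glycolysis, lysosome, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, genes of mitochondrial DNA, G1/S, G2/M, p53 targets, NRF2 targets, heat shock, immediate early genes, inflammatory genes, interferon-induced genes, pH regulation, extracellular matrix, mTOR pathway, FOXO targets, MondoA targets, epithelial markers, leukocyte markers and housekeeping genes. Of these 28 had more than 1 tested gene and were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Of 18 clock genes 16 were tested, since HLF and CIART lay below the filter.

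The genes named were set by a rule. It took every tested clock gene. For the acid effect it took the 10 largest increases and 10 largest decreases with at least 5 FPKM in the higher group and 1 direction at 13 times, and up to 2 increases and 2 decreases per list. For the rhythm at pH 7.4 and for its difference it took the 10 smallest p outside the clock list, and for pH 6.3 the 5 smallest, with at least 5 FPKM. For the plate set difference it took the 5 largest in each direction, with at least 5 FPKM. TXNIP, MYC, DDIT4 and SESN2 were always named. Outside the rule only HLF and CIART are named, and a few genes that it took are not reported here.

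The steps were checked on simulated data with the 11849 genes and known changes in 200 of them, 100 of each size. The acid test recovered 94% of changes of 1 on the log2 scale and 41% of changes of 0.5. For the plate set difference these were 31% and 1%, for the rhythm at pH 7.4 97% and 57% at those amplitudes, and for the rhythm difference 84% and 28%. The simulated rhythms gave 165 calls at pH 7.4 against 5 in the data, which loosens the adjusted threshold, so those shares are not the recovery in the data. The simulated acid and plate set changes gave 142 and 33 calls against 7074 and 2026 in the data, so their shares do not carry over either. Simulated noise was independent between genes and libraries. With no rhythm simulated at pH 6.3, limma called 0 genes. Alternatives covered the pseudocount, the filter, scaling, the trend term, the period, each time point left out, each plate set alone and the fit without the time point as a block. After the data had been seen, a correction for GC content was added (a natural spline with 5 degrees of freedom per library), as were fits without 4 or 6 libraries, and fits with a quadratic trend, a plate set step or each pH alone with the GC correction. The 1260 orders of the 7 harvests and the 60 orders of the 6 phases of a day at pH 7.4 were also added then. The 4 libraries were the 2 farthest from their time neighbours (pH 7.4 at 28 h and pH 6.3 at 20 h) and the 2 of lowest depth. That choice kept pH 7.4 at 44 and 48 h, whose GC correlations of −0.54 and −0.63 are also beyond 0.5 in size, so the fit without 6 libraries leaves these out too. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3. Genes whose reads near-identical copies share are named as uncertain.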

Results

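Polyadenylated RNA of U2OS cells, an established human osteosarcoma line that here carries a luciferase reporter driven by the promoter of the clock gene ARNTL (BMAL1), was sequenced over 52 h after a change to neutral medium (pH 7.4) or acidic medium (pH 6.3). Each medium held 0.1 µM dexamethasone, a synthetic glucocorticoid that sets the clocks of cultured cells to a common phase. There were 26 libraries in 2 groups of 13, with 1 library per pH at every 4 h from 4 to 52 h. The 4 to 24 h samples and the 28 to 52 h samples came from different sets of plates, and both media were present in each set. No time point had a second library of the same pH, so the SD and the p-values below measure the spread over time points, which holds real change over time as well as noise. All values are FPKM as deposited, with n = 13 per pH, and fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values.

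The table held 19806 gene rows, of which 11849 had a mean of at least 1 FPKM and were tested. Total counts are not part of the table. The spacing of the low FPKM values gave an estimate of 61.4 to 105 M fragments (M for mega) for 24 libraries, and of 9.71 M for pH 7.4 at 12 h and 11.1 M for pH 6.3 at 8 h. Between 3301 and 4615 genes were listed at 0 in a library. In pH 7.4 at 28 h the deviation of each gene from its mean correlated with its GC content across genes at r = 0.65, and in pH 6.3 at 20 h at r = 0.58. In pH 7.4 at 48 h the same correlation was −0.63, and at 44 h −0.54. Genes are not independent replicates, and these correlations describe single libraries.

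**Figure D1:**
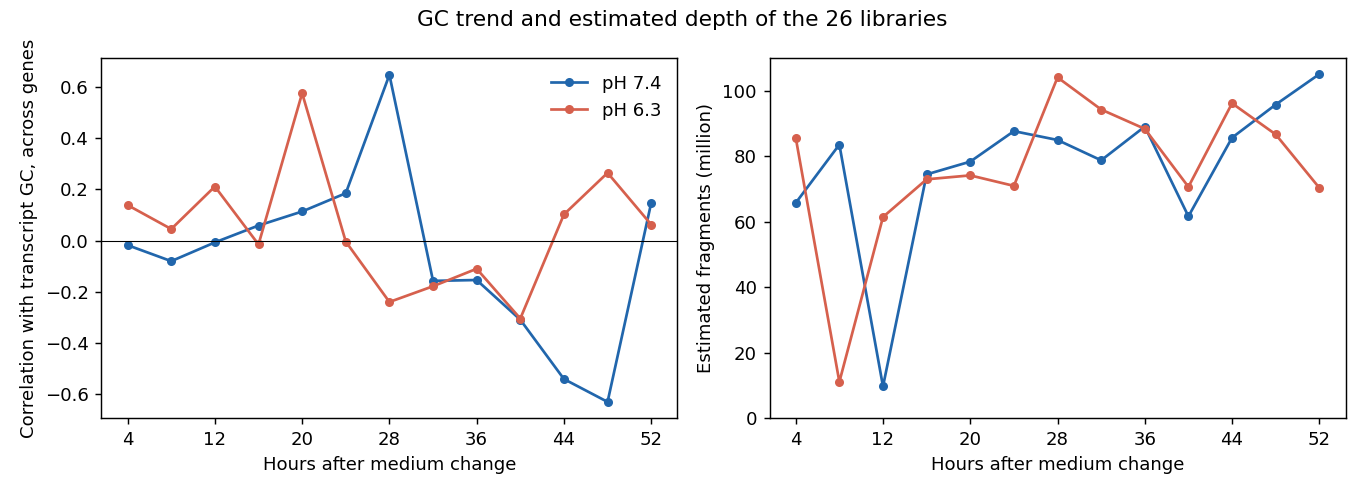
GC correlation (Pearson r across genes, no unit) and estimated depth (M fragments) of each of the 26 libraries against hours after the medium change, by pH. The highest GC correlation, 0.65, belongs to pH 7.4 at 28 h, and the lowest depth, 9.71 M fragments, to pH 7.4 at 12 h.

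The first comparison asked which transcripts differed between acidic and neutral medium over the whole course. TXNIP, which encodes an inhibitor of thioredoxin and of glucose uptake, showed the largest increase, from 4.08 ± 1.83 FPKM at pH 7.4 to 200 ± 73.6 FPKM at pH 6.3 (SD, n = 13). TSC22D3, the glucocorticoid-induced leucine zipper, rose from 11.6 ± 6.83 to 243 ± 145 FPKM. PDK4, a kinase that restrains pyruvate dehydrogenase, rose by 2.70 on the log2 scale, the secreted matrix protein gene CYR61 by 2.46 and the phosphatase gene DUSP1 by 2.45. KRT81 rose by 2.28, with reads that near-identical keratin genes can share, the stress-induced transcription factor gene ATF3 by 2.27, the repressor gene BCL6 by 2.25 and CCDC9 by 2.25. A row named MALAT1 was higher by 3.83, but its identifier (ENSG00000279576) was not matched in the annotation used, so its transcript is uncertain. All of these were higher at pH 6.3 at 13 of 13 times.

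By the same rule FAM111B, which encodes a protease linked to DNA replication, showed the largest decrease, from 20.6 ± 1.65 to 2.84 ± 3.19 FPKM (SD, n = 13). The chemokine gene CCL2 fell from 155 ± 75.6 to 30.4 ± 9.42 FPKM. The adhesion gene CNTN1 fell by 2.09 on the log2 scale, IGFL4 by 2.08, GLIPR1 by 2.06, the arginine methyltransferase gene PRMT6 by 2.06, LFNG by 1.98, SETMAR by 1.98, the replication initiation gene MCM10 by 1.96 and STEAP1 by 1.88. Each was lower at pH 6.3 at 13 of 13 times. By name, TXNIP (ENSG00000265972) lies on chromosome 1 from 145992435 to 145996600, TSC22D3 (ENSG00000157514) on chromosome X from 107713221 to 107777342, FAM111B (ENSG00000189057) on chromosome 11 from 59107185 to 59127410 and CCL2 (ENSG00000108691) on chromosome 17 from 34255218 to 34257203, in GRCh38.

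In limma's moderated test with the time point as a block, 2653 genes were higher and 4421 lower at pH 6.3 at an adjusted p below 0.05, 59.7% of those tested. For TXNIP the log2 difference was 5.21 (SE 0.20, adjusted p = 9.04e-11), for TSC22D3 4.00 (SE 0.38, adjusted p = 6.48e-07), for FAM111B −2.74 (SE 0.20, adjusted p = 6.89e-08) and for CCL2 −2.18 (SE 0.20, adjusted p = 4.84e-07). A change of at least 2-fold was seen for 404 higher and 664 lower genes, and 525 higher and 970 lower genes kept 1 direction at 13 of 13 times. Within 4 to 24 h alone 1015 genes were higher and 2144 lower, and within 28 to 52 h alone 3196 and 4308. Of these, 801 were higher in both sets of plates, against 273.8 for independent lists, and 1715 were lower in both, against 779.5. For TXNIP the difference was 4.68 within 4 to 24 h and 5.66 within 28 to 52 h. The share of calls that were higher was 37.5% with the deposited FPKM and 48.1% after quantile normalization, which moved the median log2 difference of all genes from −0.12 to −0.02, a shift of 0.11. Of the genes named below, ADM, ASIC1, AURKA, DDIT4, EGLN3, FEN1, GNL3, HSPE1, INSIG2, JUN, LCP1, LIF, LOX, NPRL2, SDHA, SLC4A7 and SREBF1 did not pass within 4 to 24 h alone (adjusted p from 0.0599 to 0.691). ADM, BAG3, FEN1, RPLP2, SCNN1A and TKT did not pass within 28 to 52 h alone (adjusted p from 0.0629 to 0.827). Without 6 libraries, the 4 with a GC correlation beyond 0.5 in size and the 2 of low depth, 2320 genes were higher and 3965 lower, and ADM, BAG3, EGLN3, FEN1, JUN, SCNN1A and SLC4A7 did not pass (adjusted p from 0.0549 to 0.170).

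**Figure D2:**
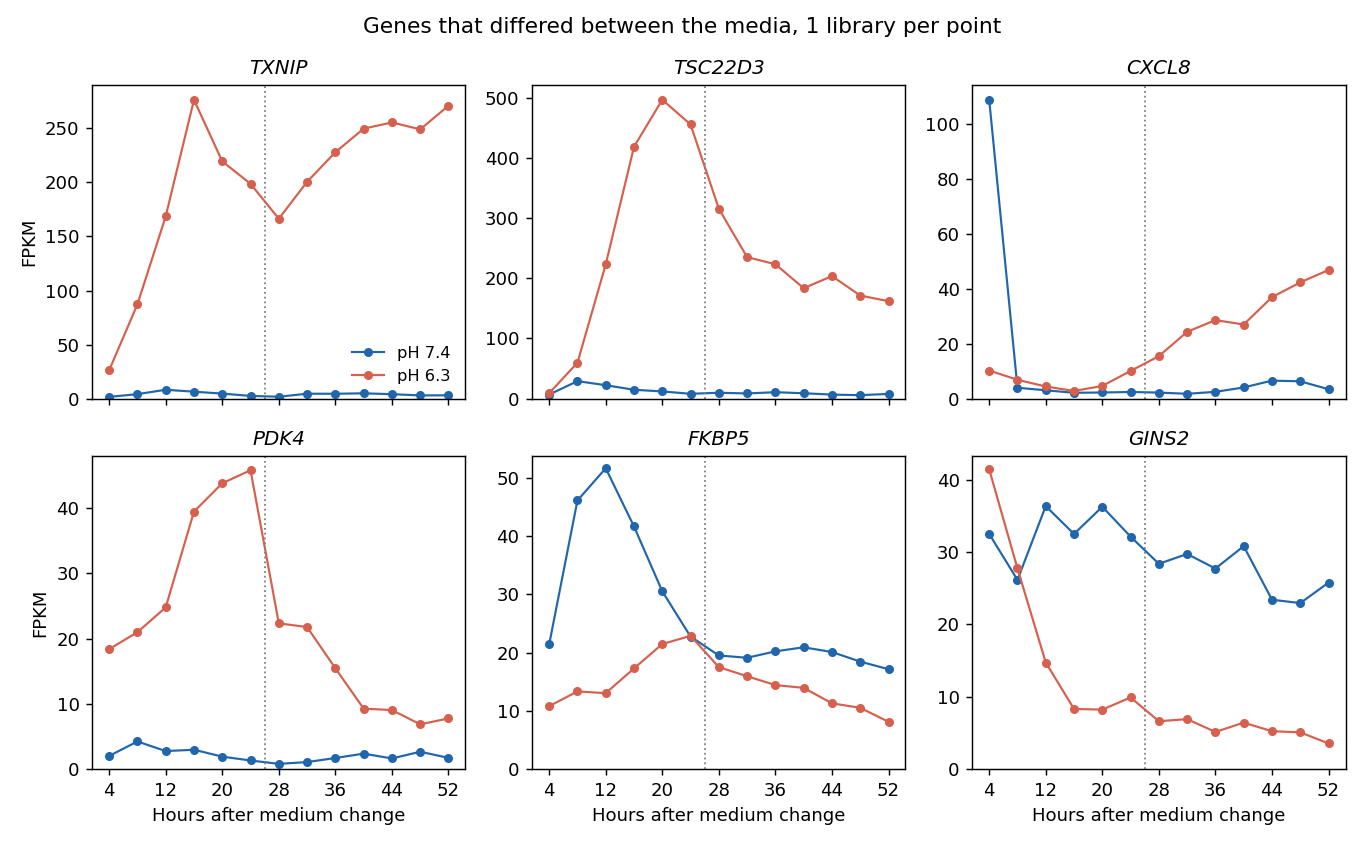
FPKM of 6 genes against hours after the medium change, 1 point per library, for pH 7.4 and pH 6.3; the dotted line separates the sets of plates. TXNIP reached 276 FPKM at pH 6.3 at 16 h and was highest at 8.17 FPKM at pH 7.4, and GINS2 was at 41.4 FPKM at 4 h and at 3.56 FPKM at 52 h at pH 6.3.

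Genes known to respond to glucocorticoids moved in both directions. Of 12 measured members 9 rose and 2 fell, with TSC22D3, DUSP1 and PDK4 higher while FKBP5, a chaperone gene and a standard glucocorticoid target, fell from 26.9 ± 11.8 to 14.7 ± 4.29 FPKM and was lower at 12 of 13 times. Adjusted over the list alone the counts were 9 and 3. At 4 h, TSC22D3 was at 6.73 FPKM at pH 7.4 and 8.99 FPKM at pH 6.3, and at 20 h at 11.9 and 497 FPKM. The list was called higher by camera with a preset correlation (adjusted p = 1.2e-04; adjusted p = 0.176 with an estimated correlation). SCNN1A, the other gene that fell (by 0.45 on the log2 scale, adjusted p = 0.0401), lost its call without the 4 libraries named above for GC content or depth (pH 7.4 at 12 and 28 h, pH 6.3 at 8 and 20 h), with an adjusted p of 0.486. It also lost it without the 8, 12, 16, 20, 24, 28 or 52 h pair, with adjusted p values of 0.080, 0.087, 0.078, 0.063, 0.060, 0.064 and 0.055.

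Of 29 measured targets of ATF4, a transcription factor of the integrated stress response, 23 rose, 1, PSPH, fell and 5 did not pass. ATF3 and the secreted stress factor gene GDF15 rose by 2.27 and 2.0 on the log2 scale, and SESN2, always reported, by 1.04 (SE 0.17). Camera gave an adjusted p of 3.1e-09 (adjusted p = 0.250 with an estimated correlation), and the median difference of the list was 0.40 within 4 to 24 h and 1.46 within 28 to 52 h. Of 16 endoplasmic reticulum stress genes 11 rose, 0 fell and 5 did not pass, with the chaperone gene HSPA5 up from 190 ± 36.5 to 629 ± 155 FPKM and HERPUD1 by 1.99 on the log2 scale (adjusted p = 5.6e-07; adjusted p = 0.176 with an estimated correlation). Of 19 p53 target genes 16 rose, 0 fell and 3 did not pass, with the cell cycle inhibitor gene CDKN1A up from 44.7 ± 9.58 to 168 ± 49.7 FPKM and CCNG1 by 1.47 on the log2 scale (adjusted p = 5.6e-07; adjusted p = 0.176 with an estimated correlation). When adjusted over the list alone, the counts higher and lower were 23 and 1, 11 and 0, and 17 and 0.

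Of 18 hypoxia genes 9 rose, with NDRG1 up by 1.71 and INSIG2 by 0.93 on the log2 scale, and 2 fell, ADM and EGLN3 (camera adjusted p = 0.00251; adjusted p = 0.103 with an estimated correlation). The calls of ADM and EGLN3 were lost after quantile normalization (adjusted p = 0.303 and 0.066), and that of ADM also without the 4 libraries (adjusted p = 0.130). Of 10 FOXO target genes 5 rose and 1 fell, with BCL6 up by 2.25 and CITED2 by 1.18 on the log2 scale (adjusted p = 0.00695; adjusted p = 0.122 with an estimated correlation). TXNIP and ARRDC4, both targets of the glucose sensor MondoA, rose, the latter by 1.96 (adjusted p = 0.00251 for the pair; adjusted p = 0.176 with an estimated correlation). Of 13 inflammatory genes 8 rose and 2 fell (adjusted p = 0.0202; adjusted p = 0.432 with an estimated correlation). CCL20 rose by 2.12 on the log2 scale while CCL2 and LIF fell by 2.18 and 0.75. For calls adjusted over the list alone, the counts higher and lower were the same as over all genes for these 4 lists, with 9 and 2, 5 and 1, 2 and 0, and 8 and 2.

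Of 23 members of the G1/S list, genes of the start of DNA replication, 17 fell, 5 did not pass and 1, FEN1, rose by 0.26 on the log2 scale. The replication gene GINS2 fell by 1.61 (SE 0.21) on the log2 scale and was lower at 11 of 13 times (camera adjusted p = 2.0e-04; adjusted p = 0.356 with an estimated correlation). Of 25 G2/M genes, which act in mitosis, 14 rose, 0 fell and 11 did not pass, with the mitotic kinase gene AURKA up by 0.85 and CDC20 by 0.76 on the log2 scale (adjusted p = 4.6e-04; adjusted p = 0.399 with an estimated correlation). Adjusted over the list alone the counts higher and lower were 1 and 18 for G1/S and 14 and 0 for G2/M. MYC, always reported, rose by 0.71 (SE 0.11), and the mTOR inhibitor gene DDIT4 by 0.87 (SE 0.17).

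Of 76 cytosolic ribosomal protein genes 72 rose and 0 fell, 74 and 0 adjusted over the list alone, with RPLP2 up by 0.85 on the log2 scale (camera adjusted p = 6.9e-21; adjusted p = 0.176 with an estimated correlation). All 13 genes encoded in mitochondrial DNA fell, also adjusted over the list alone, among them MT-CYB by 0.90 and MT-CO3 by 0.86 on the log2 scale (adjusted p = 4.7e-06; adjusted p = 0.250 with an estimated correlation). They took up 19.6% ± 1.54 of the summed FPKM at pH 7.4 and 13.8% ± 1.37 at pH 6.3 (SD, n = 13), lower at pH 6.3 at 13 of 13 times. After quantile normalization 54 ribosomal protein genes were higher and 1 lower, and 1 mitochondrial gene was higher and 7 were lower. The median log2 difference of the ribosomal protein list then went from 0.45 to 0.29 and that of the mitochondrial list from −0.47 to −0.24. The difference of RPLP2 was then 0.71, that of MT-CYB −0.88 and that of MT-CO3 −0.24. Both families share reads with many near-identical copies, so their values are uncertain.

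**Figure D3:**
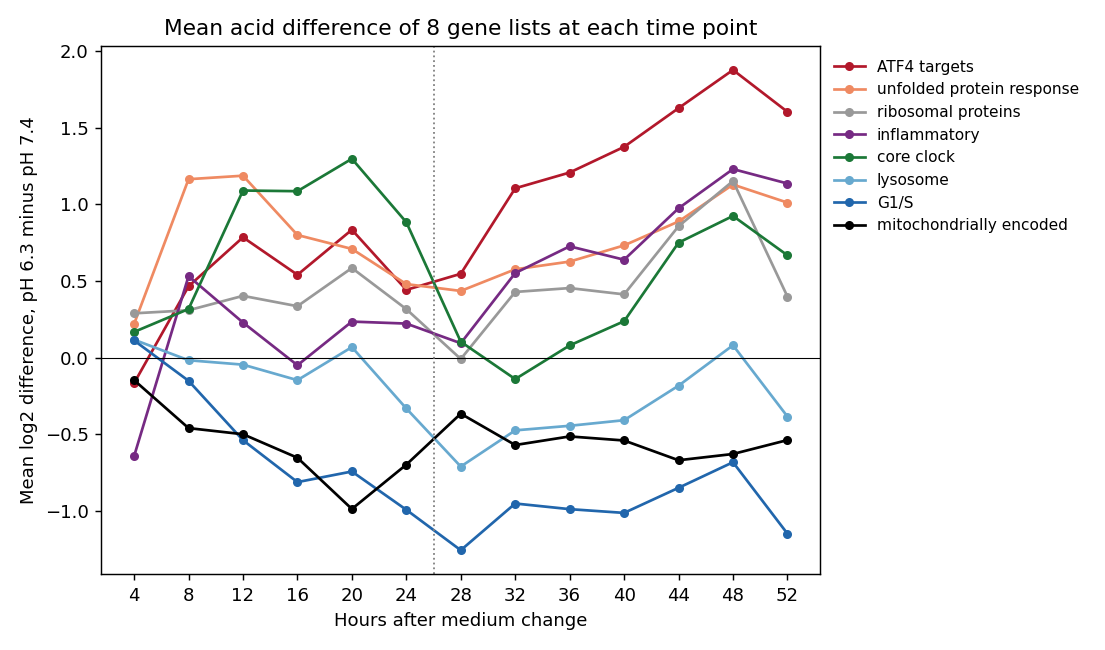
Mean log2 difference (pH 6.3 minus pH 7.4, log2(FPKM + 1) scale) of the members of 8 gene lists against hours after the medium change; the dotted line separates the sets of plates. The ATF4 target list was at −0.17 at 4 h and 1.88 at 48 h, and the G1/S list at 0.11 at 4 h and −1.26 at 28 h. Of 28 lists 12 were highest at 48 h and 10 lowest at 28 h, times at which the pH 7.4 library had a strong GC correlation, and after correction for GC content 9 of the 12 and 8 of the 10 still were.

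Apart from the core clock list, which is described with the clock, camera called none of the other lists tested, although single members changed. Of 24 cholesterol synthesis genes 6 rose, with SQLE up by 0.65, and 8 fell (adjusted p = 0.504). The median of that list was −0.02 while camera ranked it as higher than other genes. Of 11 fatty acid synthesis genes 2 rose, with ELOVL5 up by 1.14, and 7 fell, with the regulator gene SREBF1 down by 0.88 (adjusted p = 0.504). Of 18 glycolysis genes 4 rose and 7 fell (adjusted p = 0.797), with the hexokinase gene HK2 up by 1.72 and the phosphofructokinase gene PFKP down by 0.85. Of 44 oxidative phosphorylation genes 12 rose and 16 fell (adjusted p = 0.761), with SDHA up by 0.53 and SDHC down by 0.66. That balance depended on the scaling, with 7 higher and 17 lower after quantile normalization and 14 and 12 after correction for GC content. Of 34 lysosomal genes 3 rose and 15 fell (adjusted p = 0.313), with the autophagy gene MAP1LC3B up by 0.66. Of 15 NRF2 targets 3 rose and 5 fell (adjusted p = 0.964), with TKT up by 0.65 and NQO1 down by 1.35. Changes of single genes in this paragraph are on the log2 scale. When adjusted over the list alone, the counts higher and lower were 6 and 8, 2 and 7, 4 and 7, 13 and 16, 3 and 15, and 2 and 4.

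Of 30 ribosome biogenesis genes 9 rose and 9 fell (adjusted p = 0.918), with GNL3 up by 0.83 and POLR1A down by 1.23 on the log2 scale. Of 27 mTOR pathway genes 8 rose and 8 fell (adjusted p = 0.676), with NPRL2 up by 1.86 and EIF4EBP2 down by 0.97. Of 13 genes of pH regulation 1 rose, SLC4A7, and 6 fell, with CA13 down by 1.04 and the acid-sensing channel gene ASIC1 by 0.98 (adjusted p = 0.504). The call of SLC4A7 was lost without the 4 libraries (adjusted p = 0.141). Of 12 interferon-induced genes 1 rose and 8 fell (adjusted p = 0.0904), with IFI44L down by 0.93. The gene that rose, USP18, by 0.72, had the opposite direction within 4 to 24 h alone. Of 15 matrix and bone genes 1, LOX, rose by 0.91 and 7 fell (adjusted p = 0.190), with COL6A3 down by 1.04. Of 11 heat shock genes 1, BAG3, rose and 3 fell (adjusted p = 0.918), with HSPE1 down by 0.57. Of 8 immediate early genes 2 rose, with FOS up by 1.32 and FOSB by 1.35, and 1, JUN, fell (adjusted p = 0.132), a call lost without the 4 libraries (adjusted p = 0.135). For calls adjusted over the list alone, the counts higher and lower were 9 and 9, 8 and 8, 1 and 6, 1 and 8, 1 and 7, 1 and 2, and 2 and 1.

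Of 10 housekeeping genes 2 rose and 5 fell (adjusted p = 0.504), with ACTB, which encodes beta-actin, down from 2545 ± 379 to 1519.9 ± 735 FPKM. Among markers of other cell types, 4 of 10 epithelial markers were measured and all 4 fell, with CLDN4 down by 1.37 on the log2 scale (adjusted p = 0.0559 for the list, 0.0349 after correction for GC content and 0.222 with an estimated correlation). The only measured leukocyte marker of 10, LCP1, fell by 1.27 and allowed no list test. Adjusted over the list alone the counts higher and lower were 2 and 5 for the housekeeping genes and 0 and 4 for the epithelial markers. Camera with a preset correlation called 13 of 28 lists for the acid effect and 0 with an estimated correlation, where 7 had an unadjusted p below 0.05. The directional rotation test fry, which does not compare a list with other genes, called 23.

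The second question was what acid did to the circadian clock, first as a mean level. Of 16 measured clock genes 8 rose and 2 fell, and adjusted over the list alone 9 rose and 3 fell. The largest increases were those of PER1, a repressor of the clock, from 8.39 ± 5.25 to 41.3 ± 33.5 FPKM, and of NR1D1 (REV-ERBα), from 4.93 ± 5.60 to 16.6 ± 9.61 FPKM (SD, n = 13). RORA rose by 1.26, CRY1 and CRY2 both by 1.12, NR1D2 by 0.88, PER2 by 0.78 and NFIL3 by 0.63 on the log2 scale. CLOCK fell by 0.52 and BHLHE41 by 0.57. ARNTL itself had a log2 difference of −0.62 (adjusted p = 0.0506), NPAS2 of −0.23, PER3 of 0.31, DBP of 0.28, TEF of 0.47 and BHLHE40 of 0.40, none past the threshold over all genes. Camera called the list higher (adjusted p = 0.0188; adjusted p = 0.217 with an estimated correlation). Without the 4 libraries the calls of PER2, NR1D2 and BHLHE41 were lost (adjusted p = 0.097, 0.052 and 0.054), and without the 6 libraries also that of CRY1 (0.321, 0.127 and 0.0797, and 0.0699 for CRY1). ARNTL passed without the 8, 28, 32, 36 or 52 h pair (adjusted p = 0.0403, 0.0358, 0.0174, 0.0252 and 0.0496), and BHLHE40 without the 4, 24, 28 or 32 h pair or the 4 libraries (adjusted p = 0.0431, 0.0272, 0.0192, 0.0445 and 0.0355). After correction for GC content ARNTL and BHLHE40 passed (adjusted p = 0.0445 and 0.0382), and BHLHE40 also with upper-quartile scaling and quantile normalization (0.0312 and 0.0461).

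Within 4 to 24 h alone PER3, DBP and TEF were higher, by 1.04, 1.23 and 1.32 on the log2 scale, and ARNTL was lower by 1.12 (adjusted p = 0.0310, 0.00872, 0.0449 and 0.0276). Within 28 to 52 h alone their differences were −0.31, −0.54, −0.25 and −0.19 (adjusted p = 0.431, 0.101, 0.596 and 0.624). The difference between the sets passed its own test for DBP, but not for PER3, TEF and ARNTL (adjusted p = 0.0623, 0.0974 and 0.201). Of the genes called over the whole course, CLOCK, CRY2, NFIL3 and BHLHE41 did not pass within 4 to 24 h alone (adjusted p = 0.0588, 0.0722, 0.840 and 0.269). PER2, CRY1, NR1D1 and NR1D2 did not pass within 28 to 52 h alone (adjusted p = 0.223, 0.05003, 0.0865 and 0.168).

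Clock genes were next tested for a 24 h rhythm at pH 7.4. Each time from 4 to 24 h was harvested together with the time 24 h later, and only 52 h had a harvest of its own, so a 24 h phase and the harvest are largely confounded. ARNTL ran from 43.1 FPKM at 20 h to 10.4 FPKM at 32 h, with a fitted log2 amplitude of 0.88 (SE 0.11) and a peak at 20.9 h. NR1D2, PER3 and TEF, which are driven by ARNTL and CLOCK, had amplitudes of 1.01 (SE 0.14), 1.10 (SE 0.17) and 1.39 (SE 0.20) with peaks at 6.6, 10.8 and 9.6 h. ZSCAN31, a zinc finger gene outside the clock list, had an amplitude of 0.62 and a peak at 14.4 h. These 5 genes passed limma's test over all genes (adjusted p = 0.00283, 0.00905, 0.0246, 0.00905 and 0.0137), and 10 clock genes passed adjusted over the list alone. NR1D1 had an amplitude of 1.31 and an adjusted p of 0.191, which became 0.0349 after correction for GC content. Of the other genes named by the rule, SEMA3C had the smallest adjusted p, 0.0850, and IFIT1, GYG1, CHI3L2, SEC61A2, PLXDC2, SLC25A27, SAGE1 and GGA2 did not pass.

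At pH 7.4 an unadjusted p below 0.05 was found for 443 genes, where 592.5 are expected by chance. Leaving out the 8, 20 or 24 h pair left 2 genes, and leaving out the 28, 36 or 40 h pair left 3. Without the 4 libraries 2 genes were called, and without the 6 libraries 3. Without the 24 h pair or the 6 libraries 6 clock genes passed adjusted over the list alone. ARNTL passed in each refit that left out 1 time point. PER3 did not pass without the 8, 20, 24, 28, 32, 36, 40 or 48 h pair (adjusted p = 0.0873, 0.224, 0.289, 0.0616, 0.0877, 0.194, 0.0707 and 0.0515). TEF did not pass without the 8, 20 or 24 h pair (0.0508, 0.131 and 0.0860), nor NR1D2 without the 8 or 20 h pair (0.0508 and 0.0998). ZSCAN31 did not pass without the 4, 12, 16, 24, 28, 36 or 40 h pair (0.113, 0.0990, 0.0603, 0.0860, 0.0923, 0.0758 and 0.0707). Without the 4 libraries PER3, TEF and ZSCAN31 did not pass (0.0849, 0.0555 and 0.139), and without the 6 libraries TEF and ZSCAN31 (0.236 and 0.464). PER3 also missed the threshold with no filter, upper-quartile scaling and quantile normalization (0.0908, 0.0552 and 0.0718). With each pH fitted alone PER3, NR1D2 and ZSCAN31 did not pass (0.148 for each), and with a plate set step added to the trend PER3 and NR1D2 (0.143 and 0.0859). NR1D2 did not pass without 4 and 8 h together (0.179). ARNTL was at an adjusted p of 0.0688 without a trend and of 0.367 on ranks, settings in which 0 genes passed. A period of 36 h, taken as a control far from circadian, gave 689 genes, and periods of 22 h and 16 h gave 0.

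**Figure D4:**
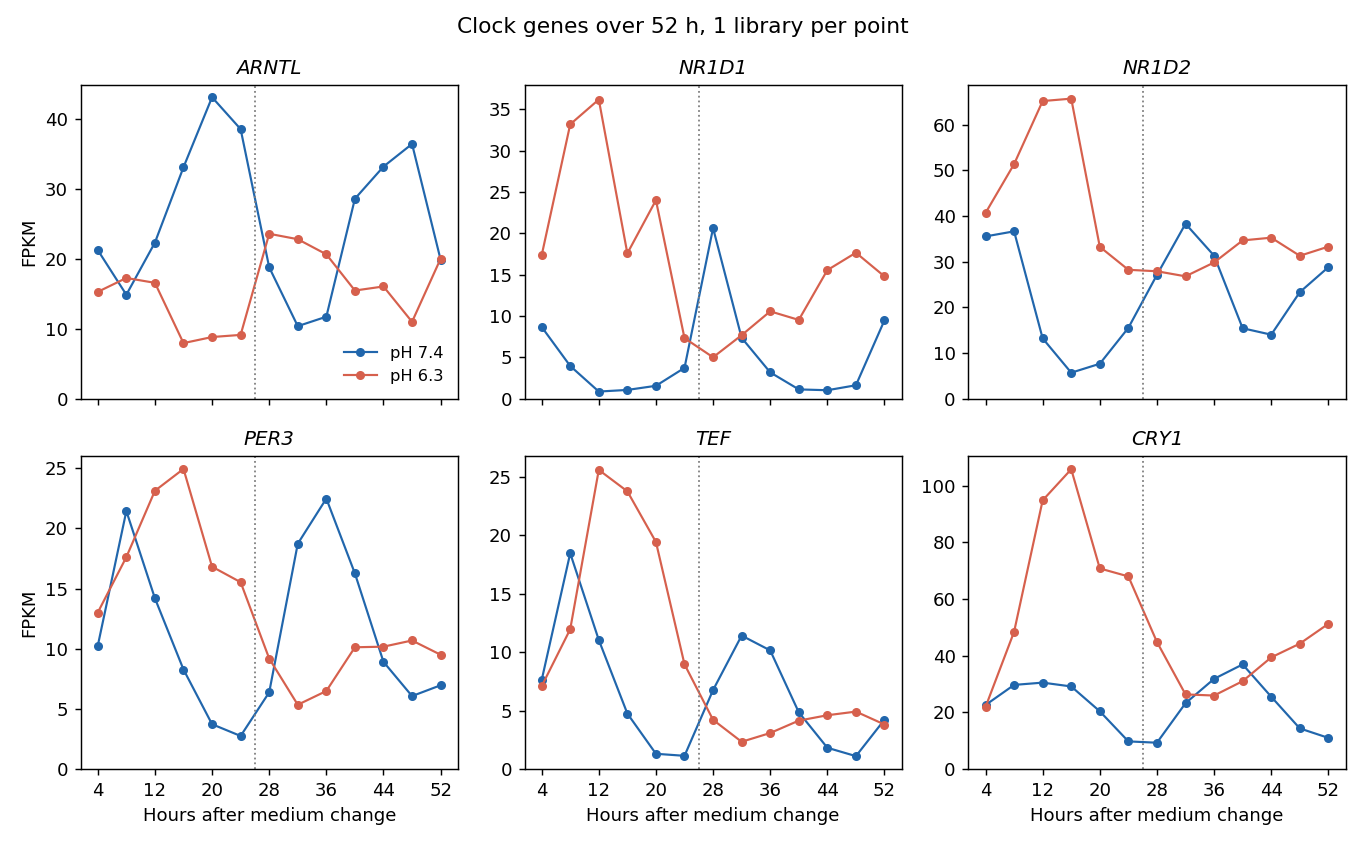
FPKM of 6 clock genes against hours after the medium change, 1 point per library, for pH 7.4 and pH 6.3; the dotted line separates the sets of plates. At pH 7.4 ARNTL ran between 10.4 and 43.1 FPKM, and at pH 6.3 between 7.93 and 23.5 FPKM.

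At pH 6.3 ARNTL ran from 7.93 FPKM at 16 h to 23.5 FPKM at 28 h, with a fitted amplitude of 0.59 and a peak at 8.4 h. NR1D1 was highest at 12 h, at 36.2 FPKM, when it was lowest at pH 7.4, at 0.852 FPKM. CRY1 reached 106 FPKM at 16 h and TEF 25.6 FPKM at 12 h. Amplitudes were 0.24 for NR1D2, 0.40 for PER3 and 0.66 for TEF, and CASK, EXOC6, ARID5B, HIST2H2BE and TIMM10B had the smallest p outside the clock list. limma called 0 genes over all genes, with 1083 at an unadjusted p below 0.05, and 0 with each pH fitted alone. When adjusted over the list alone, 5 clock genes passed, and 8 after correction for GC content. That count was 1 without the 8, 16, 20 or 32 h pair or the 4 or 6 libraries, 8 without the 40 h pair and 12 without the 52 h pair.

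The rhythm itself differed between the media for ARNTL (adjusted p = 1.4e-04) and TEF (adjusted p = 0.0163), in a test of amplitude and phase together. Their amplitudes were larger at pH 7.4 by 0.29 and 0.73. The fitted peak of ARNTL was at 20.9 h at pH 7.4 and 8.4 h at pH 6.3, and that of TEF at 9.6 and 18.7 h. At pH 6.3 neither gene passed limma's rhythm test over all genes (adjusted p = 0.542 for both). Adjusted over the list alone both did (0.00118 and 0.0210), so their peaks at pH 6.3 are less certain. Differences in amplitude and in phase were not tested separately. For calls adjusted over the list alone, 11 of 16 clock genes differed, and 6 without the 6 libraries. The amplitude was larger at pH 7.4 for 11 of 16, with medians of 0.64 and 0.41. PER3, NR1D2 and ZSCAN31 had adjusted p values of 0.0968, 0.0796 and 0.0617 and passed after correction for GC content, which raised the count from 2 to 5. C3orf67, IFIT1, PQLC3, SYTL3, RFK, LDB1, RALGDS and RTP3, among the genes with the smallest p outside the clock list, did not pass, although PQLC3 did without the 40 h pair (adjusted p = 0.0142). An unadjusted p below 0.05 was found for 1098 genes. Without the 16, 20, 24, 36 or 48 h pair, or the 4 or 6 libraries, 1 gene was called, and without the 52 h pair 6. TEF lost its call without the 8, 16, 20, 24, 32, 36 or 48 h pair (adjusted p = 0.063, 0.074, 0.311, 0.112, 0.167, 0.081 and 0.056). It also lost it without the 4 or 6 libraries, with no filter, without a trend, with a plate set step added to the trend, without 4 and 8 h together and on ranks (0.157, 0.325, 0.0934, 0.649, 0.525, 0.0564 and 0.310). With a period of 22 h ARNTL and TEF did not pass (0.554 for both). ZSCAN31 passed without the 8, 32 or 52 h pair (0.028, 0.044 and 0.028), and NR1D2 and PER3 without the 52 h pair (0.012 and 0.026).

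The last comparison asked whether the acid effect differed between 4 to 24 h and 28 to 52 h, which are also the sets of plates, so that hours and plates are confounded. SAA1 and SAA2, acute phase genes that share reads, gained most, with differences of 3.16 (SE 0.63) and 3.42 (SE 0.57) on the log2 scale. SAA1 was at 1.25 FPKM at 4 h and at 522 FPKM at 52 h at pH 6.3. CXCL8, a chemokine gene, had an acid effect of 0.10 early and 2.78 late, and the pH 7.4 library at 4 h alone held 109 FPKM. C8orf4 gained 3.0 and ALG14 2.85. The chemokine gene CXCL14 lost 3.05, with 111 FPKM at 4 h and 4.05 FPKM at 52 h at pH 6.3, and FMNL2, HMGA2, FABP7 and CDH12 had differences of −2.34, −2.20, −2.19 and −2.12. HMGA2 changed direction, from 0.98 early to −1.22 late. Among clock genes DBP had an effect of 1.23 early and −0.54 late (adjusted p = 0.0058), and NFIL3 of −0.06 early and 1.22 late (adjusted p = 0.00553).

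limma's interaction test called 1249 genes with a higher and 777 with a lower acid effect from 28 h on. Of the 20 genes with the largest acid effect 4 differed, CYR61, BCL6, CNTN1 and GLIPR1. Camera called 10 lists, ATF4 targets higher later (adjusted p = 2.2e-07; adjusted p = 0.603 with an estimated correlation), ribosomal proteins and inflammatory genes higher later (0.0195 and 0.0388; adjusted p = 0.730 and 0.650 with an estimated correlation), and the G1/S, lysosomal, cholesterol, heat shock, glycolysis, matrix and housekeeping lists lower later. Their adjusted p values were 1.8e-04, 1.8e-04, 0.00334, 0.0156, 0.0195, 0.0200 and 0.0195, and with an estimated correlation the adjusted p values were 0.603, 0.391, 0.603, 0.391, 0.650, 0.650 and 0.391. The ribosomal protein list was at −0.01 at 28 h, 1.15 at 48 h and 0.40 at 52 h, and the inflammatory list at 1.23 at 48 h and 1.14 at 52 h. Both were highest in the 48 h pair, whose pH 7.4 library is GC-biased. With values corrected for GC content both were still highest at 48 h, each at 1.16. After correction for GC content camera called the same 10 lists, and without the 6 libraries 9 of them, all but glycolysis (adjusted p = 0.0675), and ribosome biogenesis as higher later (adjusted p = 0.0123). With an estimated correlation 0 lists were called by camera and 3 had an unadjusted p below 0.05. Without the 12 h pair 792 genes had a higher and 500 a lower later effect, without the 8 h pair 509 a lower one, and without the 4 libraries 398 and 299. Without the 6 libraries, which leaves 7 pairs, 2 genes had a higher and 0 a lower later effect, and 43 of 100 other draws that left out as many pairs of each set gave 2 genes or fewer (median 143). The median size of the 2026 differences was then 0.72 (median SE 0.24), against 0.82 (median SE 0.20) with all pairs, and 100% kept their direction. These genes were picked with all pairs, the 7 among them, so their kept direction and size are not an independent check. None of the 10 genes with the largest differences named above passed, with SAA2 at 2.96 (SE 0.67) and CXCL14 at −2.85 (SE 0.49), and adjusted p values from 0.0562 to 0.113.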

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

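The tests of the libraries that stand apart, the correction for GC content, the fit without 6 libraries, the use of the fit of pH 7.4 alone and of simulated rhythms to test an explanation, and the tests of the harvests and phases, were chosen only after the results were seen. The fit of pH 7.4 alone was itself planned, and the other tests below were set before. Of these, the step and slope tests of the plate set difference used values corrected for GC content. A difference between the sets of plates, or between the media in rhythm, drew attention to each result here.

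The acid effect was higher from 28 h on for 1249 genes and lower for 777. The later minus the earlier effect on the log2 scale was 3.42 for SAA2, 3.16 for SAA1, 3.0 for C8orf4, 2.85 for ALG14 and 2.69 for CXCL8. It was −3.05 for CXCL14, −2.34 for FMNL2, −2.20 for HMGA2, −2.19 for FABP7 and −2.12 for CDH12. Of the 20 genes named for a large acid effect, all with 1 direction at every time, 4 differed. Lists that differed, with camera's adjusted p, were cholesterol synthesis (0.00334), ATF4 targets (2.2e-07), glycolysis (0.0195), lysosome (1.8e-04), ribosomal proteins (0.0195), G1/S (1.8e-04), heat shock (0.0156), inflammatory genes (0.0388), extracellular matrix (0.0200) and housekeeping genes (0.0195), none of them with an estimated correlation, where 3 had an unadjusted p below 0.05. The rhythm, with amplitude and phase tested together, differed between media for 2 genes. The amplitude was larger at pH 7.4 by 0.29 for ARNTL and by 0.73 for TEF. Their fitted peaks were at 20.9 and 9.6 h at pH 7.4 and at 8.4 and 18.7 h at pH 6.3, where neither rhythm passed over all genes.

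The first pattern weighed is the different acid effect in the 2 sets of plates, called for 2 genes without 6 libraries, where 43 of 100 other draws that left out as many pairs gave 2 or fewer. A batch step between the sets as the whole cause is argued against by values corrected for GC content, a correction chosen after the results were seen. With it, the median effect of the called genes was turned toward their later difference. That median moved by 0.181 between 24 and 28 h and by up to 0.256 within a set, a difference of −0.0750. GC content of the libraries is argued against as the whole cause, since 97.9% of the called genes stayed past the threshold after correction for it. Within 4 to 24 h alone, also with values corrected for GC content, 86.6% of the called genes moved toward their later difference. A gradual change with hours in acid predicts this. For independent genes 50% is expected by chance. These genes share the same libraries and were picked by their later difference, so the share is not a test against chance. A batch that adds to a gradual change also remains open, because hours and plates are confounded. Of 100 draws of the plate set label over time points only the real one, 1, gave as many genes as 2026, with 441 as the highest other. The draws scatter the label, while the real sets are unbroken runs of hours, so any smooth drift favours the real one. They also ignore that times 24 h apart were harvested together. Chance is therefore not excluded for the count.

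The second pattern is that 2 libraries, pH 7.4 at 28 h and pH 6.3 at 20 h, lay farther from the mean of their time neighbours than the 20 others with neighbours on both sides (distances 0.454 and 0.465, against at most 0.393); the 4 libraries at 4 and 52 h were not compared. Shallow sequencing is argued against, because the deeper of the 2 ranked 15 of 26 in estimated depth. A change specific to 1 time and medium remains open. Their deviations correlated across genes at 0.754, above the highest of 155 other pairs that differ in both by 0.182. These deviations were not corrected for GC content, however, and the 2 libraries had the highest GC correlations (0.65 and 0.58). A shared GC trend alone can raise that value, so it does not decide the question. GC content as the cause remains open, since after correction the farther one still lay at 1.07 times the farthest other library, a gap smaller than the SD of 0.0493. An earlier bound, any ratio above 1, would have excluded GC content as the whole cause, and it was replaced by this bound after the value was seen because it took no account of that spread.

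For the third pattern, the small number of 5 rhythmic genes at pH 7.4, GC content and the spread borrowed from pH 6.3 both remain open as causes, because correction for the first gave 6 genes, pH 7.4 fitted alone gave 2 and both changes together gave 10. By the earlier rule, which read each change singly, both were argued against, and that rule was replaced after the values were seen because the changes act together. Genes of large amplitude were few, since only 6 of the 11849 tested had a fitted amplitude of at least 1, and 3 of these passed. Whether their lack accounts for the small count stays open. The recovery of 97% of simulated genes of amplitude 1 came with 165 calls, which loosens the threshold. The times from 4 to 24 h were each harvested with the time 24 h later. Of the 5 genes 2 also differed in rhythm from pH 6.3, harvested with them. With the correction for GC content, chosen after the results were seen, all 5 did in limma's rhythm difference test (adjusted p from 2.9e-04 to 0.0388). Since the 2 fits differ in this, a harvest effect stays open. Of 100 random orders of the time points 3 gave at least 5 genes, with 58 as the highest other, but these orders also break up the harvests.

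Of 1260 orders of the 7 harvests at pH 7.4, with 52 h as a harvest of its own, 3 gave at least 5 genes, the real one among them, with 8 as the highest other. Of 60 orders of the 6 phases of a day, with times 24 h apart kept together and 52 h thus beside 4 and 28 h, only the real one, 1, gave as many as 5, with 3 as the highest other. Few orders of either kind gave as many, but both tests were added after the count was seen. Both also scatter neighbouring hours, so any smooth drift over the hours favours the real order. Chance is thus not excluded for the count of 5, and neither is an effect of the harvest itself. Of 100 swaps of the pH label within time points only the real one, 1, gave as many genes as the 7074 of the acid effect, with 0 as the highest other. The swaps treat the time points as independent, although each set of plates gave several and times 24 h apart were harvested together. They also put the acid effect itself into the spread, so few calls could come from them. Chance is thus made less likely for the acid effect but is not excluded. For the rhythm at pH 6.3 limma called 0 genes, with 1083 at an unadjusted p below 0.05, so that all 100 of 100 random orders of the time points had to give as many (highest other 614) and nothing follows about chance. For the difference in rhythm 16 of 100 swaps of the pH label gave at least 2 genes, so chance is not excluded, and the highest other was 3514. Swapped labels put the acid effect itself into the courses, which is a structure of the samples.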

How the results depend on the processing

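The GC correction, the fits without 4 or 6 libraries and the quadratic, GC plus plate set step and GC plus single-medium fits were chosen only after the results were seen; the cause of each change was not tested, except where fewer samples enter. Over 3106 pairs of 120 named genes and settings, the acid effect kept its direction and side of the threshold in 2959, passed no longer in 122, newly passed in 20 and reversed in 5. The reversals were NFIL3 (−0.0643) and USP18 (−0.0556) within 4 to 24 h alone, and PER3 (−0.31), DBP (−0.54) and TEF (−0.25) within 28 to 52 h alone. The plate set difference of the 10 named genes kept its call in 240 of 250 and lost it for all 10 without the 6 libraries. Without the time point as a block the acid counts were 2687 higher and 4496 lower, and the plate set counts 1666 and 1053. Without the block ARNTL and BHLHE40 gained a call (adjusted p = 0.0117 and 0.0215), and SCNN1A, ACSS2, ADM and FEN1 were among those that lost one. Short RNA classes were not in the table, so keeping them changed nothing and has no value. For the acid effect, a pseudocount of 0.1 gave 1138 genes at least 2-fold lower; 4 to 24 h alone gave 1015 higher and 2144 lower, and 247 at least 2-fold higher; 28 to 52 h alone gave 782 and 1085 at least 2-fold. For the plate set difference, GC correction gave 1173 lower, a linear interaction 1277 lower, the fit without 4 libraries 398 higher and 299 lower, and that without 6 libraries 2 and 0. Lists called fell from 13 and 10 to 0 and 0 with an estimated correlation, and fry called 23 and 6. In the rhythm tests the counts that moved were as follows, for all genes at pH 7.4, at pH 6.3 and for the difference, then for the clock list alone. Without a trend pH 7.4 had 0 genes, with 2 clock genes at pH 6.3 and 6 for the difference. A trend with a plate set step gave 3, difference 1, and clock counts of 0 at pH 6.3 and 6 for the difference; the step alone gave a difference of 4. A period of 22 h gave 0 and difference 0, with clock counts of 0 and 4; 26 h gave 8, 1 and 11, with 11 clock genes at pH 6.3; 16 h gave 0 and 0, with clock counts of 0, 0 and 0; 36 h gave 689, 4271 and 3173, with 12 clock genes at pH 6.3. Ranks gave 0, difference 1 and 1 clock gene at pH 6.3. Each pH alone gave 2, with 1 clock gene at pH 6.3. Leaving out 4 and 8 h gave a difference of 1 and 3 clock genes at pH 6.3. An adjusted p below 0.01 gave 3 and difference 1; no filter gave difference 1. GC correction gave a difference of 5 and 8 clock genes at pH 6.3; a quadratic trend 9 and 10. GC with a quadratic trend gave 9, difference 10 and 12 clock genes at pH 6.3; GC with a step a difference of 6; GC with each pH alone 10, with 1 clock gene at pH 6.3. Without the 4 libraries the counts were 2, difference 1, and 1 clock gene at pH 6.3; without the 6 libraries 3, difference 1, and clock counts of 6, 1 and 6. Leaving out each time point gave ranges of 792 to 1628 and 500 to 1025 for the plate set difference, 2 to 5 for the rhythm at pH 7.4, 0 to 0 at pH 6.3 and 1 to 6 for the difference, with clock counts of 6 to 11, 1 to 12 and 8 to 14. For the acid effect those ranges were 2425 to 2787 and 4179 to 4594, and 343 to 506 and 622 to 870 for 2-fold. Estimated depths of 9.71 and 11.1 M fragments limit the low values of 2 libraries.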

Other observations

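The test of the clock genes' spread was chosen only after the courses had been seen. From 28 h on, the SD of the clock genes over time was smaller at pH 6.3 than at pH 7.4 for 14 of 16 genes, with a median log2 ratio of −0.79 after GC correction, against −0.11 over all genes. The hypothesis that clock genes cycle with smaller excursions in acid from 28 h on was tested against 10000 random lists of the same size and mean expression, and the median lay at the 0.45 percentile. The test measures the same spread in the same courses that prompted it, so it describes the pattern and adds no support for the hypothesis. The 4 to 24 h period also lay at the 0.45 percentile, with a median of −0.06 against 0.63 over all genes. In that period 9 of 16 clock genes had a smaller SD. The difference is thus not specific to the later hours, and its sign there is not shown by the ratio alone.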
